A study of Mus musculus with 9 samples.

How the data were processed

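Total RNA from mouse liver was extracted with Trizol and made into sequencing libraries with a commercial RNA-seq kit, per the labels' protocols. Reads were placed on the mouse genome build mm10, per the submitters' processing notes. The aligner, the counting tool, the annotation release and the use of strand are not given in the sources used here. The authors deposited 1 table of TPM, in which reads are divided by gene length and scaled to the same total in each library. Per the file headers each of its 32248 lines has a gene ID, a symbol, exon coordinates and an exon length. Among the deposited lines, 452 belong to 168 gene IDs that are listed under several symbols, with repeated values. The TPM columns reach their common total only with those repeats. Here 1 line per gene ID was kept, which left 31964 gene IDs. Of these, 31915 are in the GENCODE M21 annotation and 31704 have the same chromosome, start and end there. The samples were grouped by the letters in their titles. The strain label of C replicate 4 differs from that of the other samples in 1 character (C57BL7J in place of C57BL6J).

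TPM keeps no depth of its own. In this table TPM multiplied by the exon length is a whole multiple of a step that is the same for all genes of a library, so the reads behind the values could be recovered. Between 99.96% and 100% of the values above 0 came within 0.1 of a whole number. Whether these are single reads or read pairs is not known. The recovered reads ran from 45597163 to 65165613 per library. Each pair of libraries differed in at least 3046 genes beyond sampling noise, so no column was taken for a second copy of another library. That check covers counting error only and does not show that libraries came from separate animals.

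The design fixed before the data were examined assumed counts and named a count test with TMM scaling. Since the values are TPM, limma took its place, and edgeR and DESeq2 were not used. The fixed fallback for values that are not counts was limma on log2(value + 1), which, read literally, uses the TPM as deposited. The TPM as deposited was also among the alternatives fixed beforehand. TMM scaling was kept for the results given first, a choice made after both had been seen, and the counts in the TPM as deposited stand beside them. TMM factors were computed from the recovered reads, trimming 30% of the log ratios and 5% of the mean levels, and applied to the TPM. The resulting divisors lay between 0.867 and 0.902 in C, 1.00 and 1.09 in A-C and 1.07 and 1.10 in M. A gene was tested if its TPM was at least 1 in at least 3 of the 9 libraries, which left 11086 genes. The test was limma (version 3.58.1, in R 4.3.3) on log2(scaled TPM + 1) with a mean per group. All 9 libraries were in 1 fit with 6 residual degrees of freedom and empirical Bayes moderation with a trend and robust settings. P-values were adjusted by Benjamini and Hochberg within each comparison at a threshold of 0.05. The overall test was limma's moderated F over the changes of A-C and M against C.

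The 43 gene lists (pathways, liver zones, sex-biased genes and markers of other cell types) were fixed before the data were examined. The 40 lists with at least 4 tested members were tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison. The T and NK cell, pancreatic acinar and adipocyte markers had 2, 1 and 2 tested members and were left out. With an estimated correlation no list was called in any comparison (smallest adjusted p 0.134, 0.189 and 0.140 for A-C versus C, M versus A-C and M versus C). The directional test fry asks whether a list's genes move one way and not how the list compares with other genes. It called 11, 2 and 3 lists. Of 999 list entries, 987 were matched to a gene ID.

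The rule for the genes named was also fixed beforehand. It took, per comparison, up to 6 genes with the largest change in each direction among those with an adjusted p under 0.05, a mean log2 CPM of at least 3 in the recovered reads and no overlap between the groups. Genes without an assigned name were left out. The rule added up to 3 called members of each list that was called or had at least 4 called members, and a fixed set of genes of alcohol and lipid metabolism, inflammation and steroid response. Not each gene that the rule allows is described. The result for 1 gene that the rule allows is not reported here. Genes outside the rule are said to be named after their values were seen.

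The fit was tested on simulated data with the mean level and spread of each of the 11086 genes. Noise was drawn independently for each gene and library. It found 79, 77 and 80 of 100 genes changed by 1 log2 and 93, 96 and 96 of 100 changed by 2 log2, for A-C versus C, M versus A-C and M versus C. Between 3.83% and 5.49% of the simulated calls were false. Variation that many genes share within a library was left out, so these shares need not hold in the real libraries. Alternatives fixed beforehand were median-of-ratios scaling, no filter, moderation without the robust setting, a fold of at least 2, the TPM as deposited, the 6 libraries of a comparison alone and leaving out each library. For the lists they were an estimated correlation and fry. Added after seeing the data were a pseudocount of 0.1, voom on the recovered reads, a filter of at least 10 recovered reads, quantile normalization, and the mean level of the acute phase list as a covariate. That covariate is itself an outcome measured in these libraries. Figures were drawn with matplotlib 3.10.9.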

Results

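RNA sequencing of mouse liver gave 9 libraries in 3 groups of 3, which the labels call C (replicates 2, 3 and 4), A-C (replicates 6, 9 and 12) and M (replicates 24, 26 and 27). The stated design concerns the NIAAA mouse model of alcoholic liver injury, in which alcohol is given in a liquid diet, and magnesium isoglycyrrhizinate (MgIG), a drug related to a liquorice compound. The labels do not say which diet or treatment the letters stand for, so the groups were compared by letter only. Nothing says that the samples of a group came from separate animals, so the p-values measure only the spread between these samples. The labels also give no batch, so a difference in handling between groups cannot be told apart from the groups themselves. The deposited values were TPM, and the reads behind them came to 45597163 to 46631110 per library in C, 52392521 to 65165613 in A-C and 53879277 to 57046246 in M. Levels below are TMM-scaled TPM as mean ± SD (n = 3). Fold changes are on the log2(TPM + 1) scale, which understates the change of low genes. Adjusted p-values come from limma over 11086 tested genes, and coordinates are on mm10.

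The libraries of A-C and M were spread out among themselves. Acute phase genes, which encode plasma proteins that the liver secretes in inflammation, took 2.35% to 3.05% of the TPM in C. Their share was 3.78%, 8.94% and 21.9% in A-C replicates 6, 9 and 12, and 4.75%, 16.5% and 12.4% in M replicates 24, 26 and 27. The first principal component carried 55.1% of the variance. It placed the C libraries at -39.9 to -33.3, A-C replicate 6 and M replicate 24 at -6.19 and -8.54, and the remaining libraries at 16.7 to 44.3. Mitochondrially encoded mRNAs took 27.6% of the TPM in C replicate 2 and no more than 15.4% in any other library. The Mup genes, which encode major urinary proteins, took 6.55 ± 1.83% of the TPM in C, 1.36 ± 0.567% in A-C and 2.14 ± 0.481% in M. An exact permutation test of this share, taken on both sides, gave p = 0.1 for A-C against C and for M against C, the smallest p that 3 against 3 allows.

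**Figure D1:**
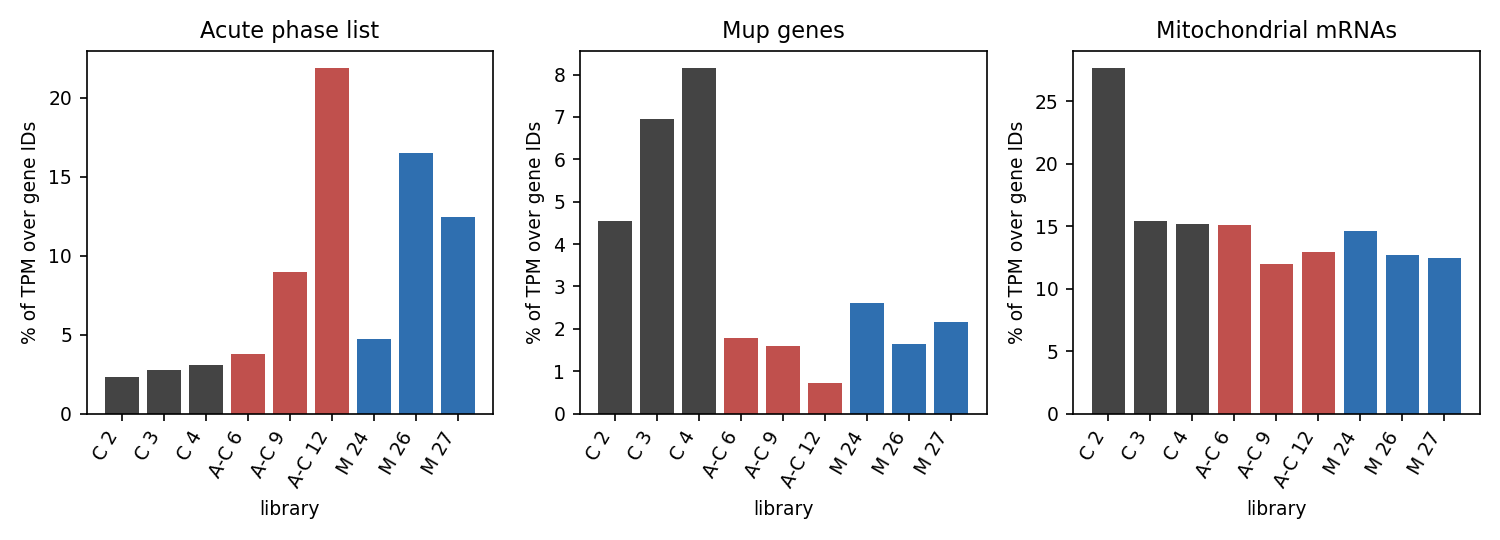
Share of the TPM over gene IDs (%, linear axis from 0) taken by the acute phase list, the Mup genes and the 13 mitochondrially encoded mRNAs, with 1 bar per library coloured by group (C grey, A-C red, M blue). The acute phase share ran from 2.35% in C replicate 2 to 21.9% in A-C replicate 12, and the highest mitochondrial share was 27.6% in C replicate 2.

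The first comparison set A-C against C. In A-C 21 of 31 male-biased genes, those higher in male than in female mouse liver, were lower than in C, and 8 of 19 female-biased genes and 10 of 38 genes of xenobiotic metabolism were higher. As lists these 3 had adjusted p = 0.701, 0.701 and 0.745 with an estimated correlation, so their camera calls at a preset correlation were lost. Cyp2b9, a cytochrome P450 gene of female liver (ENSMUSG00000040660, chromosome 7, 26173411 to 26210661), stood at 39.2 ± 6.25 in A-C and 0.0174 ± 0.0301 in C (log2 fold change 5.29, SE 0.14, adjusted p = 2.2e-07). Cyp2b10, an inducible cytochrome P450 gene, stood at 65.2 ± 2.62 against 0.876 ± 0.953 (log2 fold change 5.25, adjusted p = 0.00172). Fasn, the fatty acid synthase gene, stood at 37.6 ± 15.1 in A-C and 186 ± 19.1 in C (log2 fold change -2.36, adjusted p = 0.00353). In all, 1076 genes were higher and 795 lower in A-C than in C. The groups did not overlap for 41.2% of the genes, where chance gives 10%. In the TPM as deposited the median change of all genes was 0.22 log2, against 0.03 after TMM scaling, and 2385 genes were higher and 404 lower. Median-of-ratios scaling gave 977 higher and 942 lower. The counts were 205 higher and 126 lower without C replicate 3, 257 and 194 without A-C replicate 9, 534 and 388 without C replicate 2, and 656 and 424 without C replicate 4. Without A-C replicate 12, 728 genes were higher and 497 lower. With the mean acute phase level as a covariate, a setting chosen after seeing the data, 738 were higher and 498 lower.

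Of 31 tested male-biased liver genes, 21 were lower in A-C than in C, 0 were higher and 10 did not pass (25 when adjusted over the list alone). Their median log2 change was -2.16 (camera adjusted p = 2.9e-14, adjusted p = 0.701 with an estimated correlation). Mup7 stood at 307 ± 154 in A-C against 5972 ± 3739 in C, Mup11 at 176 ± 99.5 against 3097 ± 1646, and Mup17 at 304 ± 164 against 4727 ± 3138. The Mup genes are near-identical copies, so the reads of single members are uncertain where the counting could split them. Cyp2u1, a cytochrome P450 gene, fell from 13.9 ± 4.51 to 2.27 ± 0.28. Selenbp2, which encodes a selenium-binding protein, fell by 5.21 log2 (adjusted p = 0.0186), a call lost without C replicate 3, C replicate 4, A-C replicate 9 or A-C replicate 12 (adjusted p up to 0.0696). The steroid dehydrogenase gene Hsd3b5 fell by 5.19 log2 (adjusted p = 0.0422). Its call was lost without any single C library, A-C replicate 9, A-C replicate 12 or M replicate 27 (adjusted p up to 0.126). Of 19 female-biased genes 8 were higher and 0 lower, 10 when adjusted over the list alone (median 0.73, and 1.12 without C replicate 2, camera adjusted p = 4.1e-05, adjusted p = 0.701 with an estimated correlation). Cyp2a22 stood at 28.9 ± 2.63 against 0.904 ± 0.278 and Cyp2a4 at 7.48 ± 0.835 against 1.59 ± 0.397. Ddx3y, a gene of the Y chromosome, lay between 24.3 and 38.7 in the 9 libraries. Xist, transcribed from the inactive X chromosome, was at 0.0559 or less, and both were named after their values were seen.

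In lipid metabolism, 7 of 24 fatty acid and triglyceride synthesis genes were lower and 0 higher, 11 when adjusted over the list alone (median -1.06, and -0.62 without A-C replicate 12, camera adjusted p = 4.8e-05, adjusted p = 0.701 with an estimated correlation). Pnpla5 and Pnpla3, which encode lipase-family proteins, fell from 1.68 ± 0.197 to 0.0841 ± 0.0565 and from 2.60 ± 1.02 to 0.353 ± 0.210 (adjusted p = 0.00172 and 0.00754). Srebf1, which encodes a transcription factor of lipid synthesis, stood at 14.7 ± 6.99 against 53.8 ± 10.2 (adjusted p = 0.0169, up to 0.0692 without C replicate 3 or A-C replicate 9). Among 36 genes of fatty acid oxidation and PPAR alpha targets 9 rose and 1 fell, 14 when adjusted over the list alone (median 0.47, camera adjusted p = 0.00326, adjusted p = 0.718 with an estimated correlation). Cyp4a14, a fatty acid hydroxylase gene, stood at 889 ± 577 against 30.7 ± 33.7, and its paralog Cyp4a10 at 589 ± 297 against 76.1 ± 42.1. Acnat2 stood at 160 ± 59.6 against 11.2 ± 3.20, and Pdk4, a pyruvate dehydrogenase kinase gene, at 22.8 ± 9.34 against 3.56 ± 1.14. Fabp1, the liver fatty acid-binding protein gene, fell from 26629 ± 6538 to 5230 ± 2188. The fatty acid transporter gene Cd36 rose from 7.91 ± 1.69 to 62.9 ± 11.9 (adjusted p = 0.00237). Plin2, which encodes a lipid droplet coat protein, rose from 90.0 ± 5.49 to 498 ± 244 (adjusted p = 0.0125, up to 0.0536 without C replicate 3 or A-C replicate 9).

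Among 38 genes of xenobiotic cytochromes P450 and conjugation 10 were higher and 0 lower, 15 when adjusted over the list alone (median 0.50, camera adjusted p = 0.0032, adjusted p = 0.745 with an estimated correlation). Without A-C replicate 6 the median of this list was 0.17 and its camera adjusted p 0.0858. Cyp3a13 stood at 328 ± 58.4 against 94.0 ± 5.25 (adjusted p = 0.0022). Of 31 NRF2 and glutathione genes 12 were higher and 1 lower, 17 when adjusted over the list alone (median 0.42, and 0.73 without A-C replicate 12, camera adjusted p = 0.0052, adjusted p = 0.701 with an estimated correlation). The glutathione transferase genes Gsta2 and Gstm3 rose from 13.6 ± 1.75 to 93.4 ± 33.3 and from 39.0 ± 5.48 to 306 ± 107. Nqo1, a quinone reductase gene, rose from 4.82 ± 0.647 to 20.1 ± 5.89. Of 23 genes typical of pericentral hepatocytes, the cells near the central vein, 9 were higher and 1 lower, 12 when adjusted over the list alone (median 0.49, camera adjusted p = 0.00301, adjusted p = 0.701 with an estimated correlation). Cyp2c29 stood at 996 ± 449 against 154 ± 26.6. Periportal genes, those of the cells near the portal vein, were lower in 3 of 23 cases and higher in 0, 6 when adjusted over the list alone (median -0.61, camera adjusted p = 0.0129, adjusted p = 0.745 with an estimated correlation). The camera adjusted p of the periportal list was 0.0757 without A-C replicate 12, and Hsd17b6, a steroid dehydrogenase gene, fell from 185 ± 8.86 to 32.1 ± 18.9. Cyp2e1, the ethanol-inducible cytochrome P450 gene, stood at 6974 ± 2055 in A-C and 6212 ± 832 in C (adjusted p = 0.721). The ethanol-metabolising genes Adh1 and Aldh2 stood at 1604 ± 510 against 1855 ± 13.8 and 1007 ± 152 against 880 ± 87.0 (adjusted p = 0.479 and 0.458).

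The acute phase list had 9 of 31 members higher and 0 lower, 18 when adjusted over the list alone (median 1.75, camera adjusted p = 9.3e-06, adjusted p = 0.701 with an estimated correlation). Serpina3m stood at 1676 ± 1063 against 201 ± 8.32, the complement gene C3 at 4055 ± 1218 against 1036 ± 140, and Stat3, which encodes a transcription factor of the acute phase response, at 42.9 ± 13.0 against 12.5 ± 1.09. Lcn2, which encodes lipocalin 2, was at 15.1, 444 and 4445 in the A-C libraries and at 8.52 ± 5.67 in C (adjusted p = 0.0933, and 0.0216 without A-C replicate 6). Neutrophil markers had a median of 1.70 over 4 tested genes without a call (camera adjusted p = 0.165). Tnf, Il1b and Ccl2, cytokine genes, stayed below the filter, at no more than 0.417, 1.49 and 2.23 in any library. Interferon-stimulated genes were lower in 5 of 31 cases and higher in 0, 9 when adjusted over the list alone (median -0.40, camera adjusted p = 0.000118, adjusted p = 0.701 with an estimated correlation). Heat shock genes were higher in 3 of 15 cases, 3 also when adjusted over the list alone (median 0.51, camera adjusted p = 0.0402, adjusted p = 0.718 with an estimated correlation). The heat shock list passed neither in the TPM as deposited (camera adjusted p = 0.0723) nor without C replicate 2, A-C replicate 6 or A-C replicate 9 (0.101, 0.0972 and 0.117). Of 23 metallothionein, iron and ferroptosis genes 5 were higher and 0 lower, 8 when adjusted over the list alone (median 0.37, camera adjusted p = 0.0146, adjusted p = 0.611 with an estimated correlation). Mitochondrially encoded mRNAs were lower in 3 of 13 cases, 6 when adjusted over the list alone (median -0.67, camera adjusted p = 0.000357, adjusted p = 0.701 with an estimated correlation). Without C replicate 2, the library with the highest share of these mRNAs, the median was -0.38.

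Among markers of other liver cells, the 4 tested B and plasma cell markers were lower, 4 also when adjusted over the list alone (median -1.37, camera adjusted p = 3.8e-05, adjusted p = 0.134 with an estimated correlation). The immunoglobulin genes Igkc and Ighm stood at 5.31 ± 1.10 against 33.3 ± 7.19 and 1.89 ± 0.349 against 6.14 ± 1.06. Endothelial markers were higher in 9 of 15 cases, 11 when adjusted over the list alone (median 0.85, camera adjusted p = 1.5e-05, adjusted p = 0.701 with an estimated correlation). Among them, Kdr stood at 9.29 ± 1.10 against 3.78 ± 0.752 and Oit3 at 25.1 ± 4.34 against 10.2 ± 3.35. Markers of Kupffer cells, the resident macrophages of the liver, were higher in 6 of 14 cases, 11 when adjusted over the list alone (median 0.54, camera adjusted p = 0.000118, adjusted p = 0.701 with an estimated correlation). Monocyte and macrophage markers were higher in 2 of 8 cases, 2 also when adjusted over the list alone (median 0.39, camera adjusted p = 0.0402, adjusted p = 0.701 with an estimated correlation). The monocyte list did not pass in the TPM as deposited, without a filter, or without C replicate 2, C replicate 4 or A-C replicate 9 (camera adjusted p = 0.0545, 0.336, 0.053, 0.0594 and 0.117). The median of the monocyte list was 0.60 in the TPM as deposited, 0.062 without a filter, and 0.30, 0.40 and 0.27 in those 3 fits. Erythroid markers were lower in 2 of 7 cases and higher in 0, 5 when adjusted over the list alone, without a call for the list (median -1.44, camera adjusted p = 0.0866). Of the 17 lists that camera called, fry passed 10 and did not pass fatty acid and triglyceride synthesis, fatty acid oxidation or acute phase proteins (each 0.0678), mitochondrially encoded mRNAs (0.0941), heat shock (0.110), interferon-stimulated (0.150) or periportal genes (0.229).

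The second comparison set M against A-C. Of 26 genes of cholesterol synthesis and uptake 8 were lower in M and 18 did not pass, and the list had an adjusted p = 0.189 with an estimated correlation. The glutathione transferase genes Gstm3 and Gstm2 were also lower in M. Sqle, the squalene epoxidase gene (ENSMUSG00000022351, chromosome 15, 59315077 to 59331192), stood at 1.15 ± 0.226 in M and 24.7 ± 5.57 in A-C (log2 fold change -3.57, SE 0.21, adjusted p = 0.000336). The ratio between the A-C and M means of Sqle was 21.5. Gstm3 (ENSMUSG00000004038, chromosome 3, 107963696 to 107969283) stood at 25.4 ± 8.69 in M and 306 ± 107 in A-C (log2 fold change -3.53, SE 0.32, adjusted p = 0.00911). Both calls held in each of the 9 fits that left out a library. By limma, 19 genes passed the test, 4 higher and 15 lower in M, and 1274 had an unadjusted p under 0.05 where 554.3 were expected by chance. The groups did not overlap for 16.2% of the genes, where chance gives 10%. Genes vary together, so these expectations hold only on average, and an excess over them does not by itself show a difference between the groups. A fit to the 6 libraries of A-C and M alone called 0 genes higher and 2 lower, and without a filter on low values 1 was higher and 5 lower. The counts were 2 higher and 5 lower without A-C replicate 6, 0 and 3 without A-C replicate 9 or M replicate 26, 1 and 4 without M replicate 27, and 7 and 23 without M replicate 24. Without A-C replicate 12, 7 genes were higher and 18 lower, and without C replicate 3, 2 and 11. With the mean acute phase level as a covariate, itself an outcome and added after seeing the data, 126 genes were higher and 131 lower.

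None of the 26 cholesterol genes was called higher in M, and 21 passed when adjusted over the list alone. Their median log2 change was -1.21 (camera adjusted p = 1.9e-29, adjusted p = 0.189 with an estimated correlation, 0.0188 with fry). Idi1, the isopentenyl diphosphate isomerase gene, stood at 1.43 ± 0.695 against 23.8 ± 7.08 (adjusted p = 0.0117). The sterol dehydrogenase gene Nsdhl stood at 3.78 ± 1.07 against 23.8 ± 8.87 (adjusted p = 0.0177), and Hmgcs1, which encodes the cytosolic HMG-CoA synthase, at 24.4 ± 1.78 against 86.4 ± 19.2 (adjusted p = 0.0176). Cyp51, Hsd17b7, Tm7sf2 and Lss, named after their values were seen, fell by 1.91, 1.52, 1.28 and 0.98 log2. Without A-C replicate 9 or M replicate 26 the calls of Idi1, Nsdhl, Hmgcs1, Cyp51, Hsd17b7, Tm7sf2 and Lss were lost, with adjusted p of up to 0.0685 for Idi1 and 0.196 for Tm7sf2. Those of Nsdhl, Hmgcs1, Cyp51, Hsd17b7, Tm7sf2 and Lss were also lost without M replicate 27, and those of the last 5 of these without A-C replicate 6. The calls of Tm7sf2 and Lss were lost without any single C library, and that of Lss in all 9 such fits (adjusted p up to 0.148). Between A-C and C, 3 of the 26 genes were higher in A-C and 1 lower (median -0.015, camera adjusted p = 0.802, adjusted p = 0.935 with an estimated correlation). Idi1 was among the higher ones, at 7.33 ± 2.91 in C, so A-C lay above both other groups for this gene.

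**Figure D2:**
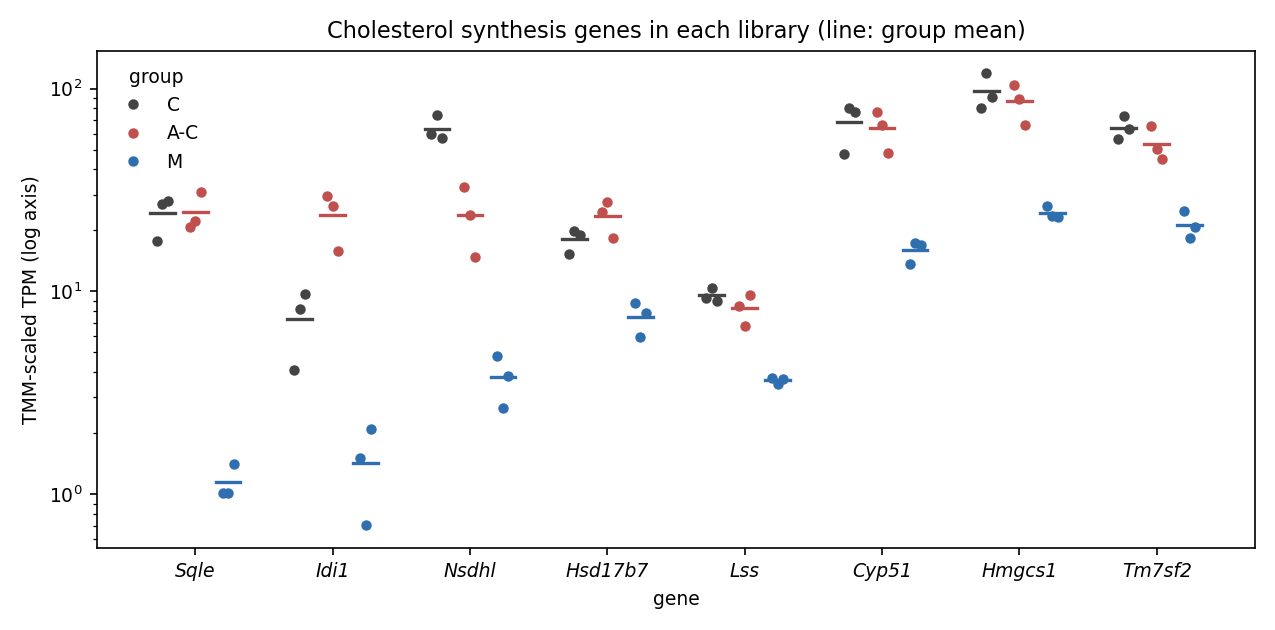
TMM-scaled TPM (log axis) in each library of the 8 cholesterol genes, of 26 tested, that were called lower in M than in A-C. The other 18 did not pass and are not shown. Each library has 1 point, with a line at the mean of each group (C grey, A-C red, M blue). The genes were picked by that call, so the separation of M from A-C follows from the choice. The M libraries lay below the A-C and the C libraries for each of the 8 genes, with Sqle at 1.15 on average in M, 24.7 in A-C and 24.3 in C.

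Outside that pathway, Gstm2 fell to 32.6 ± 10.8 in M from 153 ± 41.1 in A-C (adjusted p = 0.0177). The steroid hydroxylase gene Cyp17a1 fell to 6.05 ± 0.962 from 46.8 ± 11.5 (adjusted p = 0.0177) and the glucuronosyltransferase gene Ugt1a5 to 3.97 ± 1.36 from 22.0 ± 2.97 (adjusted p = 0.00912). Reads of the Gstm genes and of the overlapping Ugt1a genes are uncertain where the counting could split them. Hmg20b, a chromatin protein gene, rose to 29.2 ± 3.41 from 13.9 ± 1.53 (adjusted p = 0.0218) and Carmil1, an actin regulator gene, to 4.27 ± 0.405 from 1.48 ± 0.507 (adjusted p = 0.0484). The call of Ugt1a5 was lost without A-C replicate 9 (adjusted p = 0.0632) and that of Gstm2 without A-C replicate 6, M replicate 26 or M replicate 27 (up to 0.0966). That of Cyp17a1 was lost without A-C replicate 6, A-C replicate 9, M replicate 26 or M replicate 27 (up to 0.0966). Hmg20b lost its call without C replicate 3, C replicate 4, A-C replicate 6, A-C replicate 9, M replicate 26 or M replicate 27 (up to 0.116), and Carmil1 in all such fits but the one without A-C replicate 12 (up to 0.201). Treh, Neu3 and 3110045C21Rik, lower in M, and Cfd and Snora30, higher in M, complete the 19 genes and were named after their values were seen. Leaving out A-C replicate 9 or M replicate 26 ended the calls of Treh, Neu3, 3110045C21Rik, Cfd and Snora30 (adjusted p up to 0.201 for Neu3). Those of Treh, Neu3, 3110045C21Rik and Cfd also ended without A-C replicate 6 or M replicate 27, those of Neu3, 3110045C21Rik and Cfd without A-C replicate 12, those of Neu3 and 3110045C21Rik without C replicate 3, and that of Neu3 in all 9 such fits.

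As lists, endothelial markers were lower in M than in A-C, with 0 of 15 called over all genes and 11 when adjusted over the list alone (median -0.57, camera adjusted p = 9.7e-11, adjusted p = 0.494 with an estimated correlation). The fibrosis and matrix list had 0 of 18 members called and 2 when adjusted over the list alone (median -0.40, and -0.26 without A-C replicate 12, camera adjusted p = 5.4e-06, adjusted p = 0.494 with an estimated correlation). Genes of the unfolded protein and integrated stress response were higher as a list, with 0 of 32 called and 1 when adjusted over the list alone (median 0.72, camera adjusted p = 0.000216, adjusted p = 0.885 with an estimated correlation). The median was 0.44 without M replicate 26, and 0.35 without A-C replicate 6, with a camera adjusted p of 0.0737. Of the NRF2 and glutathione list only Gstm3 and Gstm2 were called over all 31 genes, 7 when adjusted over the list alone (median -0.01, mean -0.34, camera adjusted p = 0.0308, adjusted p = 0.885 with an estimated correlation). The median of that list turned to 0.036 in the TPM as deposited, 0.028 without A-C replicate 6 and 0.0083 without A-C replicate 9. It was -0.10 without A-C replicate 12, -0.080 without M replicate 24 and -0.079 without M replicate 27. Its camera adjusted p was 0.0794 without C replicate 2, 0.187 without A-C replicate 6, 0.089 without M replicate 24 and 0.0669 without M replicate 26. Male-biased genes were higher as a list, with 0 of 31 called and 1 when adjusted over the list alone (median 0.50, camera adjusted p = 0.00638, adjusted p = 0.918 with an estimated correlation), but not without A-C replicate 12 or M replicate 24 (0.591 and 0.624). The median of the male-biased list was 0.15 and 0.054 in those fits and 0.81 without A-C replicate 6.

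Kupffer cell, monocyte, stellate cell and MHC class II lists had camera adjusted p of 0.000377, 0.00076, 0.00184 and 0.000433, with lower medians in M (-0.34, -0.36, -0.24 and -0.38). Their adjusted p = 0.75, 0.494, 0.794 and 0.696 with an estimated correlation. None of their 14, 8, 14 and 8 members was called over all genes, and 0, 1, 0 and 0 were when adjusted over the list alone. Without M replicate 24 the stellate list had a camera adjusted p of 0.0588, and without A-C replicate 9 the Kupffer list had a median of -0.19. The metallothionein, iron and ferroptosis list had 0 of 23 members called and 2 when adjusted over the list alone (median -0.23, and -0.34 without A-C replicate 12, camera adjusted p = 0.00076, adjusted p = 0.189 with an estimated correlation). Erythroid markers had 0 of 7 members called and 5 when adjusted over the list alone, without a call for the list (median 1.36, camera adjusted p = 0.0900). Camera called 11 lists in all between M and A-C, and 23 without A-C replicate 12, but 0 with an estimated correlation (smallest adjusted p 0.189). Fry passed 2 of the 11, the cholesterol list and that of metallothioneins, iron and ferroptosis (0.0281), and the other lists had fry adjusted p of 0.149 to 0.728. The acute phase list was not called (median 0.17, camera adjusted p = 0.398). For Fasn the levels were 21.1 ± 3.59 in M and 37.6 ± 15.1 in A-C (adjusted p = 0.392), for Plin2 259 ± 98.6 and 498 ± 244 (adjusted p = 0.476), and for Cyp2e1 7755 ± 1457 and 6974 ± 2055 (adjusted p = 0.840).

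The third comparison set M against C. In M 17 of 26 cholesterol genes, 8 of 24 fatty acid and triglyceride synthesis genes and 18 of 31 male-biased genes were lower than in C. Of the genes of fatty acid oxidation and PPAR alpha targets 10 of 36 were higher, of those of xenobiotic metabolism 10 of 38, and of the acute phase genes 12 of 31. Each of these 6 lists had an adjusted p = 0.901 with an estimated correlation, so that their camera calls at a preset correlation were lost. Sqle stood at 1.15 ± 0.226 in M and 24.3 ± 5.68 in C (log2 fold change -3.54, adjusted p = 0.00012) and Nsdhl at 3.78 ± 1.07 against 63.5 ± 9.02 (-3.77, adjusted p = 0.000636). Fasn stood at 21.1 ± 3.59 against 186 ± 19.1 (-3.09, adjusted p = 0.00228) and Cyp2b9 at 41.6 ± 3.55 against 0.0174 ± 0.0301 (5.38, adjusted p = 1.9e-07). There were 1032 genes higher and 745 lower in M than in C, and the groups did not overlap for 41.6% of the genes. In the TPM as deposited the median change of all genes was 0.27 log2, against 0.05 after TMM scaling, and 2931 genes were higher and 351 lower. Median-of-ratios scaling gave 867 and 884, and without a filter on low values 589 genes were higher and 500 lower. The counts were 121 higher and 70 lower without M replicate 27, 129 and 75 without C replicate 3, 316 and 272 without C replicate 2, and 348 and 199 without M replicate 26. They were 547 and 373 without C replicate 4, 574 and 430 without A-C replicate 9, and 539 and 238 with the mean acute phase level as a covariate.

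Of the 26 cholesterol genes 17 were lower in M than in C and 0 higher, 21 when adjusted over the list alone (median -1.38, camera adjusted p = 7e-13, adjusted p = 0.901 with an estimated correlation, 0.00681 with fry). Hmgcs1 stood at 24.4 ± 1.78 against 96.9 ± 19.8. Of 24 fatty acid and triglyceride synthesis genes 8 were lower and 0 higher, 9 when adjusted over the list alone (median -0.67, camera adjusted p = 1.8e-05, adjusted p = 0.901 with an estimated correlation). The desaturase gene Fads1 stood at 41.9 ± 19.6 against 317 ± 41.7 and Pnpla5 at 0.0246 ± 0.0281 against 1.68 ± 0.197. Among the 36 genes of fatty acid oxidation and PPAR alpha targets 10 rose and 1 fell, 16 when adjusted over the list alone (median 0.44, camera adjusted p = 0.0206, adjusted p = 0.901 with an estimated correlation). The camera adjusted p of that list was 0.0951 in the TPM as deposited, with a median of 0.72, and 0.195 without M replicate 24. Acadvl, an acyl-CoA dehydrogenase gene, stood at 160 ± 18.2 against 40.4 ± 13.8 and Cyp4a10 at 604 ± 112 against 76.1 ± 42.1. Cyp4a14 stood at 461 ± 162 against 30.7 ± 33.7 (adjusted p = 0.0122, up to 0.0594 without C replicate 3 or M replicate 27). Cd36 rose from 7.91 ± 1.69 to 38.2 ± 15.9 (adjusted p = 0.00833). Plin2 stood at 259 ± 98.6 against 90.0 ± 5.49 (adjusted p = 0.0528), and at adjusted p = 0.0204, 0.0358 and 0.02 without A-C replicate 6, A-C replicate 12 or M replicate 24. The apolipoprotein genes Apoa1 and Apoa4 fell from 33829 ± 3721 to 9875 ± 2388 and from 483 ± 95.2 to 138 ± 17.9. Of the 20 lipoprotein genes 4 were lower and 1 higher, 5 when adjusted over the list alone, without a call for the list (camera adjusted p = 0.176).

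Male-biased genes were lower in 18 of 31 cases and higher in 0, 21 when adjusted over the list alone (median -1.80, camera adjusted p = 5.1e-11, adjusted p = 0.901 with an estimated correlation). Mup17 stood at 242 ± 49.3 against 4727 ± 3138 and Cyp2u1 at 2.69 ± 0.846 against 13.9 ± 4.51. Mup20 stood at 2484 ± 846 against 24394 ± 7979 (adjusted p = 0.0102, and 0.0505 without C replicate 3). Hamp, which encodes the iron hormone hepcidin, fell by 3.63 log2 (adjusted p = 0.0427, and by 2.32 without M replicate 24), a call lost without any single C library, A-C replicate 9, M replicate 26 or M replicate 27 (adjusted p up to 0.122). Of 19 female-biased genes 6 were higher and 1 lower, 9 when adjusted over the list alone (median 0.57, camera adjusted p = 0.00255, adjusted p = 0.901 with an estimated correlation). In the TPM as deposited the camera adjusted p of the female-biased list was 0.0934. Cyp2a22 stood at 21.1 ± 2.94 against 0.904 ± 0.278. In the xenobiotic list 10 of 38 rose and 0 fell, 11 when adjusted over the list alone (median 0.46, camera adjusted p = 0.0023, adjusted p = 0.901 with an estimated correlation, and a median of 0.27 with camera adjusted p = 0.112 without M replicate 24). Cyp2c29 stood at 1335 ± 383 against 154 ± 26.6 and Cyp2b10 at 36.9 ± 26.7 against 0.876 ± 0.953. Periportal genes were lower in 5 of 23 cases and higher in 1, 7 when adjusted over the list alone (median -0.57, camera adjusted p = 0.00201, adjusted p = 0.901 with an estimated correlation). Arg1, the arginase gene of the urea cycle, fell from 2299 ± 335 to 1012 ± 172. The urea cycle and amino acid list had 1 of 26 members lower and 0 higher, 1 also when adjusted over the list alone (median -0.24, camera adjusted p = 0.0497, adjusted p = 0.901 with an estimated correlation). Its median turned to 0.039 in the TPM as deposited, and was -0.47, -0.11 and -0.14 without M replicate 24, M replicate 26 and M replicate 27. Its call was lost with median-of-ratios scaling, without a filter, and without C replicate 2, C replicate 3, C replicate 4, M replicate 26 or M replicate 27 (camera adjusted p = 0.0663, 0.104, 0.0876, 0.0515, 0.0566, 0.33 and 0.177).

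Acute phase genes were higher in M than in C in 12 of 31 cases and lower in 0, 19 when adjusted over the list alone (median 2.10, camera adjusted p = 7.3e-07, adjusted p = 0.901 with an estimated correlation). Complement factor B, Cfb, stood at 6.49 ± 2.49 against 0.957 ± 0.312, C3 at 4361 ± 1466 against 1036 ± 140 and Stat3 at 49.4 ± 19.0 against 12.5 ± 1.09. The 4 tested neutrophil markers had a median of 1.77 without a call (camera adjusted p = 0.204). Orm2, an orosomucoid gene, rose by 4.88 log2 (adjusted p = 0.0495) and the metallothionein gene Mt1 by 3.48 (adjusted p = 0.048). Both calls were lost without any single C library, A-C replicate 9, M replicate 26 or M replicate 27 (adjusted p up to 0.175 and 0.157). The unfolded protein and integrated stress response list had 4 of 32 members higher and 0 lower, 4 also when adjusted over the list alone (median 1.01, camera adjusted p = 0.000442, adjusted p = 0.901 with an estimated correlation). Interferon-stimulated genes were lower in 4 of 31 cases and higher in 1, 5 when adjusted over the list alone (median -0.37, camera adjusted p = 0.000773, adjusted p = 0.901 with an estimated correlation). Of 8 MHC class II and antigen presentation genes 2 were lower and 0 higher, 4 when adjusted over the list alone (median -0.40, camera adjusted p = 0.0358, adjusted p = 0.901 with an estimated correlation). That list did not pass without C replicate 3, C replicate 4, M replicate 26 or M replicate 27 (camera adjusted p = 0.0602, 0.0569, 0.0637 and 0.0788). Mitochondrially encoded mRNAs had 0 of 13 members called and 7 when adjusted over the list alone (median -0.65, and -0.36 without C replicate 2, camera adjusted p = 0.000256, adjusted p = 0.901 with an estimated correlation). The 4 B and plasma cell markers were lower, 4 also when adjusted over the list alone (median -1.22, camera adjusted p = 3.8e-05, adjusted p = 0.140 with an estimated correlation). Igkc stood at 4.63 ± 1.42 against 33.3 ± 7.19. Gsta2 stood at 85.0 ± 8.05 against 13.6 ± 1.75. Gstm3, set beside it after its values were seen, stood at 25.4 ± 8.69 in M and 39.0 ± 5.48 in C (adjusted p = 0.183). The 7 erythroid markers had a median of -0.06 with 0 called, 0 when adjusted over the list alone (camera adjusted p = 0.646). Of the 14 lists that camera called between M and C, fry passed 3, those of cholesterol, female-biased and B and plasma cell genes. The male-biased, acute phase, fatty acid synthesis and xenobiotic lists had a fry adjusted p of 0.0914 each, and the remaining 7 had 0.166 to 0.457.

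**Figure D3:**
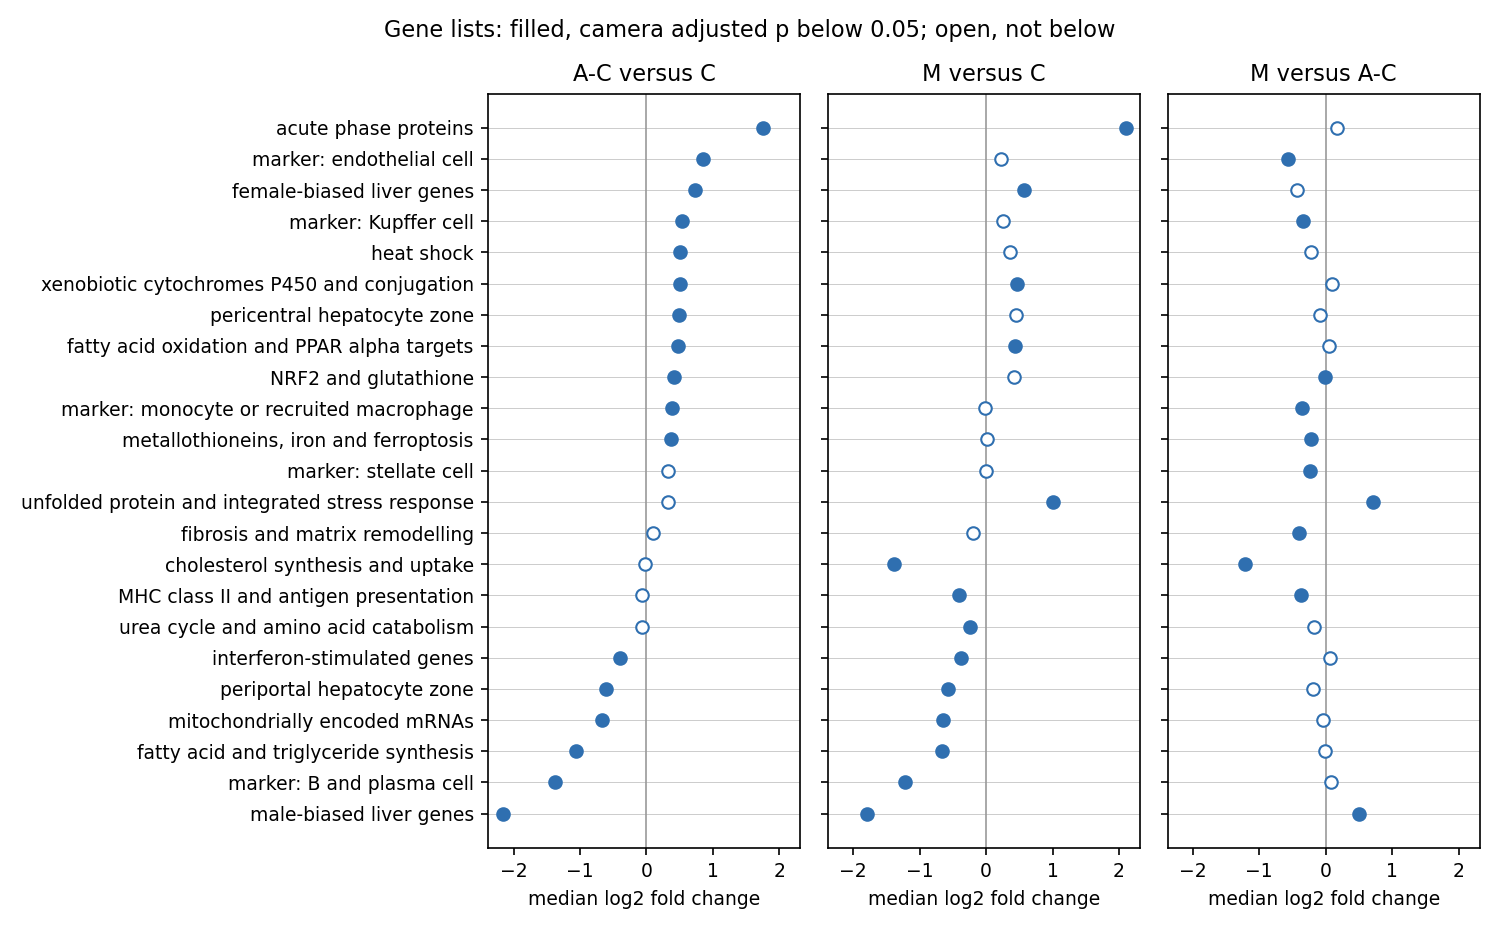
Median log2 fold change (horizontal axis, TMM-scaled values) of the gene lists called in at least 1 comparison, with 1 panel per comparison, where filled points have a camera adjusted p below 0.05 at the preset correlation and open points do not, and no list was called with an estimated correlation. The cholesterol list lies at -1.38 for M versus C (adjusted p = 0.901 with an estimated correlation) and -1.21 for M versus A-C (adjusted p = 0.189 with an estimated correlation).

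Across the 3 groups together 1754 genes differed (limma's moderated F-test), and 3113 in the TPM as deposited. Group C stood apart from both A-C and M for 1038 genes, 430 of them higher and 608 lower in C, such as Fasn and Cyp2b9. Each C library also had fewer reads (at most 46631110) than each library of A-C and M (at least 52392521). With no batch in the labels, a difference in handling of the C samples cannot be told apart from the group. Group A-C stood apart for 10 genes, among them Gstm3, Gstm2 and Ugt1a5 on the high side and Hmg20b and Carmil1 on the low side. Group M stood apart for 12 genes, 11 of them lower, including Sqle, Nsdhl, Hmgcs1 and Cyp17a1. These counts rest on comparisons that share libraries. In 20 simulated sets of unchanged groups there was at most 0 such gene. That noise was independent between genes, so hardly any such gene could arise, and the 0 does not measure chance in these libraries. Independent lists of the same sizes would overlap in 53.4 and 100.2 genes on the high and low side for C. For A-C the overlaps would be 1.46 and 0.287, and for M 0.372 and 1.01. Across genes, which are not independent replicates, the change from C to A-C and the change from C to M had a Pearson r of 0.840, against 0.498 in the simulated groups. Their covariance was 0.284 against 0.0288. With 3 C libraries the group could not be split into parts of at least 2, so part of the excess may come from the shared libraries. Without C replicate 3 the 1754 and 1038 genes became 148 and 117, without C replicate 2 552 and 366, without C replicate 4 662 and 572, and without A-C replicate 9 595 and 285. They became 960 and 412 without M replicate 26 and 758 and 171 without M replicate 27. The 10 genes of A-C and 12 of M became 2 and 1 without A-C replicate 9 or M replicate 26, 4 and 1 without M replicate 27, 5 and 3 without A-C replicate 6, and 3 and 6 without C replicate 3. Without M replicate 24 the 12 genes of M became 22. In the TPM as deposited C stood apart for 2012 genes. With the mean acute phase level as a covariate, chosen after seeing the data, C, A-C and M stood apart for 518, 79 and 53 genes. Without a filter on low values 968 genes differed among the groups, and C, A-C and M stood apart for 664, 4 and 3.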

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

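The pseudocount, voom, read filter, quantile and acute phase settings were chosen after seeing the data. DESeq2, listed before the data were examined, was not run, and voom was the test run on the recovered reads. No paired analysis was possible because the groups share no replicate numbers. No called gene among those tabulated for the text changed direction under the alternatives run, but the medians of 2 called lists did. In all, 617 gene values and 102 list values kept their direction and lost their call, and 17 values of uncalled genes gained one. Of the genes picked by the naming rule or named later, 47 of 92 calls for A-C versus C, 2 of 19 for M versus A-C and 26 of 74 for M versus C passed in each of the 9 fits that left out a library. Of the lists, 13 of 17, 7 of 11 and 10 of 14 did. The cause of these changes was not tested. Depth leaves counting error, which is largest for genes below a few TPM.

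Leaving out a library gave 205 to 1226 genes higher and 126 to 967 lower in A-C than in C, 0 to 7 higher and 3 to 23 lower in M than in A-C, and 121 to 1415 higher and 70 to 1096 lower in M than in C. It gave 148 to 2490 genes differing among the 3 groups, and 117 to 1346, 2 to 15 and 1 to 22 setting C, A-C and M apart. Camera then called 16 to 19 lists for A-C versus C, 10 to 23 for M versus A-C (23 without A-C replicate 12) and 12 to 15 for M versus C, against 17, 11 and 14 with all libraries. With an estimated correlation it called 0, 0 and 0, and fry 11, 2 and 3. In the TPM as deposited, 2385 genes were higher and 404 lower in A-C than in C, 2931 and 351 in M than in C, 3113 differed among the groups and 2012 set C apart. Without a filter, which means more genes tested, 1 gene was higher and 5 lower in M than in A-C, and 589 were higher and 500 lower in M than in C. In that fit 968 differed among the groups, and 664, 4 and 3 set C, A-C and M apart. A fold of at least 2 left 273 higher and 231 lower in A-C than in C, 246 and 206 in M than in C and 234 setting C apart. The 6 libraries of A-C and M alone gave 0 higher and 2 lower. A pseudocount of 0.1 gave 9 genes higher and 19 lower in M than in A-C and 16 setting A-C apart. Voom called 2 higher and 13 lower in M than in A-C, and for A-C versus C 1098 higher and 767 lower. With the acute phase covariate 738 genes were higher and 498 lower in A-C than in C, and 126 higher and 131 lower in M than in A-C. With it 539 were higher and 238 lower in M than in C, and 518, 79 and 53 set C, A-C and M apart.

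The median of the called NRF2 and glutathione list (M versus A-C) turned to 0.036 in the TPM as deposited and ran from -0.10 to 0.028 over the fits without a library. That of the called urea cycle list (M versus C) turned to 0.039 in the TPM as deposited. The genes that changed direction had no call. As log2 changes, median-of-ratios scaling gave -0.0062 for Adh1 (M versus A-C) and -0.051 for Hsd11b1 (M versus C), and quantile normalization -0.037 for Adh1 (M versus A-C). The TPM as deposited gave 0.038 for Scd1 and 0.032 for Hsd11b1 (A-C versus C), 0.033 for Fkbp5 (M versus A-C), and 0.013 for Adh1 and 0.076 for Cpt1a (M versus C). The acute phase covariate gave 0.18 for Adh1, 0.15 for Cyp7a1, -0.28 for Lcn2 and 0.24 for Hsd11b1 (A-C versus C), and -0.65 for Lcn2 and -0.020 for Hmox1 (M versus A-C). For M versus C it gave 0.24 for Adh1, 0.18 for Srebf1, 0.21 for Cpt1a, 1.23 for Cyp7a1, -0.66 for Cidec and -0.93 for Lcn2. Over the fits without a library, A-C versus C ran from -0.091 to 0.31 for Cyp2e1, -0.42 to 0.033 for Adh1, -0.36 to 0.062 for Scd1 and -0.43 to 0.061 for Hsd11b1. M versus A-C ran from -0.30 to 0.15 for Adh1, -0.32 to 0.52 for Cyp4a10, -0.63 to 1.78 for Cyp7a1, -1.99 to 2.06 for Lcn2, -0.31 to 0.60 for Hmox1, -0.056 to 0.44 for Hsd11b1 and -0.14 to 0.094 for Fkbp5. M versus C ran from -0.39 to 0.019 for Cpt1a and -0.080 to 0.11 for Hsd11b1. Those in the TPM as deposited follow from leaving out the TMM divisors, the only step that differed. This raised the median of all genes by 0.18 log2 for A-C versus C, 0.041 for M versus A-C and 0.22 for M versus C. The cause of the other changes of direction was not tested.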

Other observations

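The tests of neutrophil RNA, depth, hepatocyte share and the uncalled cholesterol genes were chosen only after the results they bear on were seen. Genes of the circadian clock went both ways between A-C and C, with 4 of 22 higher and 4 lower, 15 when adjusted over the list alone, and no call for the list (camera adjusted p = 0.141). Arntl, which encodes the clock activator BMAL1, stood at 4.94 ± 0.867 in A-C and 0.598 ± 0.620 in C (n = 3 each, limma adjusted p = 0.00415). Dbp, a clock output gene, stood at 6.03 ± 6.13 against 50.9 ± 22.6 (adjusted p = 0.0164, up to 0.0685 without C replicate 3 or A-C replicate 9). Times of day of collection are not given in the sources used here. In methionine and one-carbon metabolism 5 of 25 genes were higher and 1 lower in A-C than in C, 7 when adjusted over the list alone (camera adjusted p = 0.14). Mat1a and Mat2a, which encode methionine adenosyltransferases, stood at 4075 ± 839 against 1660 ± 109 (adjusted p = 0.00536) and 14.2 ± 2.47 against 3.66 ± 0.157 (adjusted p = 0.00172). In glycolysis and gluconeogenesis 5 of 27 were higher and 1 lower, 7 when adjusted over the list alone (camera adjusted p = 0.818). Pgk1, a glycolysis gene, stood at 263 ± 19.9 against 99.8 ± 22.4 (adjusted p = 0.00425) and Pcx, the pyruvate carboxylase gene, at 279 ± 26.6 against 154 ± 14.4 (adjusted p = 0.0118). Against C, group M had 4 of 22 clock genes higher and 3 lower, and 6 of 25 methionine genes higher and 0 lower. In glycolysis and gluconeogenesis 5 of 27 were higher in M than in C and 1 lower. Between M and A-C these lists had 0 members called over all genes, and 0, 1 and 6 when adjusted over the list alone. Camera called the lists in neither comparison.

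Acute phase genes differed widely between libraries of the same group. Saa1, which encodes serum amyloid A1, was at 19.8, 1261 and 13440 TPM in A-C replicates 6, 9 and 12 and at 173, 9915 and 5432 in M replicates 24, 26 and 27. RNA brought by neutrophils is argued against as the source, since the total of their markers rose over C by at most 0.0816% of the rise of the acute phase total. Markers also on the acute phase list were left out. The marker total itself was higher in the same libraries, at 47.1 and 60.9 in A-C replicates 9 and 12 and 65.5 and 54.6 in M replicates 26 and 27. It was 4.58 in A-C replicate 6, 5.44 in M replicate 24 and 1.73 to 8.08 in C. A difference in neutrophils between the libraries therefore stays open. Reads differed by at most a factor of 1.24 within a group while the acute phase share differed by up to 5.78. A share of the TPM does not scale with depth, so this comparison could not decide on depth. An unequal response of the mice stays open as an untested biological explanation, as does any difference in handling.

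Of 26 cholesterol genes 8 were lower in M than in A-C, and a lower share of hepatocyte RNA is argued against by the hepatocyte markers (median log2 change -0.075 against -1.21 for the cholesterol list). A single library is argued against as the source of the list's median, which stayed at -0.98 or below over the 9 fits without a library (camera adjusted p at most 1.5e-22 at the preset correlation, 0.189 with an estimated correlation of 0.440). The calls of single genes were less firm, since 7 of the 8 were lost without A-C replicate 9 or M replicate 26. Members that did not pass the test had a median of -1.05, but they were split off by the outcome itself, so this does not decide whether the whole pathway or a few genes moved. What group M received stays open as an untested explanation.

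In the TPM as deposited, 85.5% of the genes called in A-C versus C were higher, against 57.5% after TMM scaling. Abundant genes that take a larger part of the TPM in C may account for much of this. Removing the mitochondrial mRNAs and Mup genes and rescaling brought the share to 64.7% (median of all genes 0.06), and removing the 20 most abundant genes brought it to 53.8% (median -0.0073). These removals do not tell whether total RNA per cell differed between the groups, which stays open.

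The 10 ways to split 6 libraries into 3 and 3 are too few for a share under 0.05. For A-C versus C, 1 of 10 splits (the real one) called as many as 1871 genes, and the highest other called 0. For M versus C, 1 of 10 called as many as 1777, and the highest other called 1. For M versus A-C, 2 of 10 called as many as 19. The highest other set A-C replicates 6 and 9 with M replicate 24 against A-C replicate 12 with M replicates 26 and 27. It called 1213 genes, which points to a structure of the samples that runs across these groups. The acute phase share of the TPM was 3.78%, 8.94% and 4.75% on the first side of that split. On the second side it was 21.9%, 16.5% and 12.4%. The cause of this structure was not tested. For the overall test, 1 of 100 drawn splits of the 9 libraries (the real one, 280 are possible) called as many as 1754 genes. The highest other called 991, and it kept the 3 C libraries together while mixing those of A-C and M. A share of 1 in 100 was the smallest that this draw could give. It makes a chance split an unlikely source of that count without excluding it, and it does not bear on A-C against M.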
